A study of Mus musculus with 12 samples.

How the data were processed

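Messenger RNA enriched with oligo(dT) beads from total RNA of 12 mouse lung cancer samples was sequenced as DNA nanoballs, per the labels' protocols. Samples were placed in 4 groups of 3 by their titles and treatment labels: NC, OTUB1_KD, Blank and SFD@M. The titles of the Blank samples carry codes that begin with KD, and the group was taken from the word Blank and the saline treatment in the labels.

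The authors deposited 1 table of 70659 transcripts with 4 values per library. Per the file headers these are estimated read counts (expected counts that need not be whole), TPM (a length-corrected share of transcripts), FPKM (fragments scaled by length and library total) and normalized read counts. The submitters' processing notes name Bowtie2, RSEM 1.3.1, DESeq2 1.4.5 and the build GRCm39, without saying which tool made which value; alignment settings and strand handling are not given in the sources used here, so antisense and overlapping genes and near-identical copies cannot be told apart beyond what the deposited counts show. The deposited normalized counts, a signal scaled by the authors, turned out to be each expected count rounded up to a whole number and multiplied by 1 factor per library: dividing by that factor gave a whole number, within a tolerance of 0.001, for 100% of values in every library. These recovered reads entered an added alternative only.

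Expected counts of a gene's transcripts were summed over its Entrez gene identifier and rounded to whole numbers. Of 19212 gene identifiers 19155 matched a symbol in the RefSeq table of GRCm38.p6, which was used for names alone because its build is not the authors'; no coordinates are given. The 57 unnamed genes held at most 0.342% of a library's counts. Totals were 16062806 to 18028828 counts per library. At this depth 3 counts over a group of 3 libraries, the floor used for genes at 0 counts, correspond to about 0.06 CPM, so ratios against such genes are lower bounds, and 1 to 3 counts are given with a 95% counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

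Each comparison of 3 against 3 libraries was fitted by itself with edgeR 4.0.16 in R 4.3.3: filterByExpr with the group, TMM factors within the comparison, and the robust quasi-likelihood test (glmQLFit, glmQLFTest), with Benjamini-Hochberg adjusted p below 0.05 as a call. The difference between the changes of the 2 experiments was an interaction contrast over all 12 libraries in 1 fit. Exact permutation tests of Otub1 used TMM-scaled log2 CPM. Levels are CPM of library totals in the account of cell markers and Otub1 and for host and Y-linked markers given without a fold change, and TMM-scaled CPM elsewhere; TMM factors were computed anew in each comparison, so the level of a gene in 1 group can differ slightly between comparisons. Gene lists were 52 sets of pathway and cell-type genes; those with at least 5 tested members were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01, and again with a correlation estimated from the data, with ranks and with fry. The groups, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The comparisons of Blank with NC and of SFD@M with OTUB1_KD, which cross the experiments, were added after the data had been seen.

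The rule for named genes took Otub1, a ferroptosis panel (Gpx4, Slc7a11, Acsl4, Tfrc, Fth1, Hmox1, Ptgs2, Aifm2) and an immunity panel (Cd8a, Gzmb, Ifng, Cd274, H2-K1) whatever their p. It added the 10 largest rises and 10 largest falls among called genes whose libraries did not overlap and whose mean was at least 1 CPM, leaving out predicted genes and receptor segments, and the members with the smallest p of each called list. For the interaction it took the 5 smallest p in each direction. Cell-type markers and other genes given as levels were named from the fixed lists.

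The tests were first tried on simulated counts drawn with the real means, library sizes and spread. For OTUB1_KD against NC (14785 genes), 21% of 2-fold and 80% of 4-fold changes were recovered, and 8 of 109 calls were false. For SFD@M against Blank (14824 genes) the shares were 80% and 97%, with 16 of 193 calls false. A DNA replication list shifted on purpose was recovered in both, and 0 lists were called in data with no change. Simulated genes varied independently of one another, so this does not test list calls where genes vary together. Only 100 genes were changed at each size, far fewer than were called in the real data, so scaling under such broad change was not tested either. The sizes in the second comparison can be measured more closely because its libraries vary less.

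Alternatives were DESeq2 size factors, upper-quartile factors and total counts in place of TMM, no filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2 of the deposited TPM or FPKM plus a pseudocount of 1 or 0.1, all 12 libraries in 1 fit, the replicate number as a block, and each library left out in turn. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.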

Results

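The series measured messenger RNA in 12 mouse lung cancer libraries that fall into 4 groups of 3. In the knockdown experiment, Lewis lung carcinoma (LLC) cells, a transplantable mouse lung tumour line, carried either a control lentivirus (group NC) or a lentivirus against Otub1 (group OTUB1_KD) before they were used to make tumours in the lungs of mice. Otub1 encodes a deubiquitinase, an enzyme that removes ubiquitin from proteins. In the treatment experiment, mice bearing tumours received saline (group Blank) or a preparation that the labels call SFD@M (group SFD@M) and do not describe further. The labels name lung cancer as the tissue of all 12 libraries, and the series title places them in work on ubiquitin removal, ferroptosis and immune therapy of cancer. Gene totals ranged from 16062806 to 18028828 counts per library. No label says that libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

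The makeup of the libraries differed sharply between groups. Ptprc, which encodes the pan-leukocyte protein CD45, stood at 206 ± 45.6 CPM, a count scaled to the library total (mean ± SD, n = 3 here and below), in the libraries labelled OTUB1_KD and 219 ± 9.29 CPM in the SFD@M libraries, against 0.0623 ± 0.108 in NC and 0.0194 ± 0.0337 in Blank. Sftpc, the surfactant protein of alveolar type 2 cells, was at 12960 ± 5381 and 14830 ± 976 CPM in those groups and at 0.0406 and 0.0581 CPM in NC and Blank. Scgb1a1, the secretory protein of airway club cells, was the most abundant gene in each library labelled OTUB1_KD or SFD@M, with 1.11% to 3.37% of counts. In the NC and Blank libraries that place was held by Eef1a1, a translation elongation factor, with 1.23% to 1.5%. Mki67, a marker of dividing cells, showed the opposite order, with 697 ± 9.02 CPM in NC and 688 ± 8.54 in Blank against 109 ± 86.3 in OTUB1_KD and 22.5 ± 12.9 in SFD@M. Genes at 1 CPM or more numbered 11295 to 11685 in NC and Blank libraries and 14208 to 14516 in the others. Across genes, on log2(CPM + 1), NC and Blank libraries correlated at r = 0.990, while NC and OTUB1_KD libraries correlated at 0.748 to 0.848 and Blank and SFD@M libraries at 0.736 to 0.740. Genes are not independent replicates. Libraries within NC and within Blank correlated at 0.999, and their counts differed by 1.32 to 2.00 times the sampling variance. That is more than counting noise alone gives, but far less than 16.8 to 31.7 times within SFD@M and 96.9 to 160 times within OTUB1_KD. Libraries as close as those of NC and Blank cannot be told apart from technical repeats. Each library entered as a separate sample. Within OTUB1_KD the correlations were 0.958 to 0.970 and within SFD@M 0.990 to 0.994. Between OTUB1_KD and SFD@M libraries they were 0.946 to 0.986. OTUB1_KD replicate 2 correlated more closely with the SFD@M libraries (0.982 to 0.986) than with its own group (0.958 and 0.970).

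**Figure D1:**
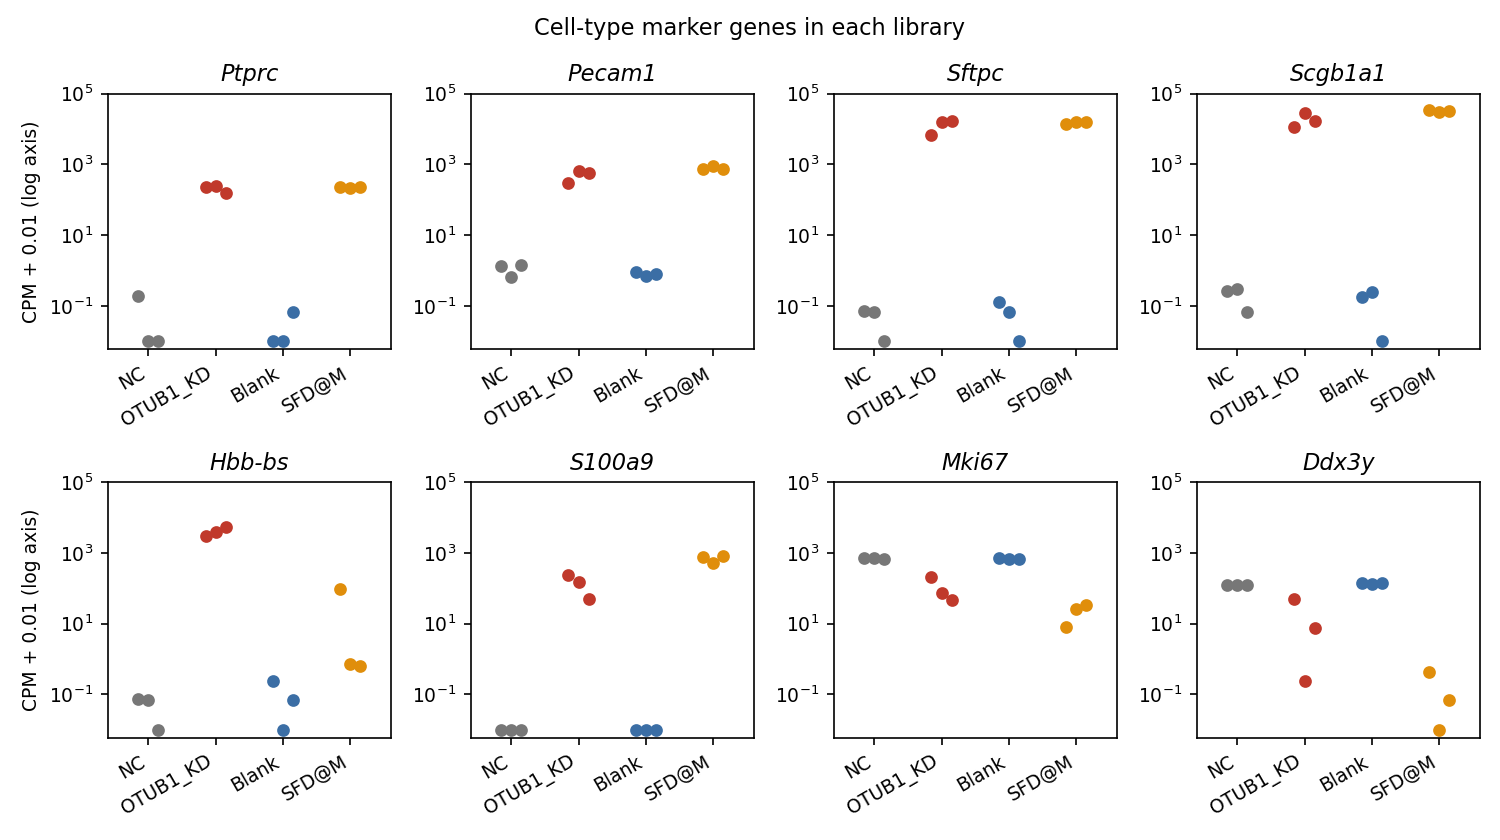
Each panel plots 1 gene, with a point per library (n = 3 per group) and CPM plus 0.01 on a log axis. The leukocyte gene Ptprc, the endothelial gene Pecam1 and the lung epithelial genes Sftpc and Scgb1a1 lie near 0 or about 1 CPM in NC and Blank libraries and at 154 to 33650 CPM in the others, while Mki67 lies highest in NC and Blank.

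Otub1, the target of the knockdown lentivirus, was at 73.3 ± 3.24 CPM in NC and 59.71 ± 11 CPM in the libraries labelled OTUB1_KD. The single values of the latter were 58.6, 49.3 and 71.2 CPM. The last of these lay within the NC range of 69.8 to 76.2 CPM, and after TMM scaling just under it, at 71.8 against 72.8 to 79.3. On the scale fitted by edgeR, Otub1 was −0.36 ± 0.18 (log2 fold change ± SE) in OTUB1_KD against NC, which did not pass the test (quasi-likelihood adjusted p = 0.112; exact two-sided permutation p = 0.1 on TMM-scaled values, the smallest that 3 against 3 allows). Otub1 passed without OTUB1_KD replicate 3 (−0.53, adjusted p = 0.015), in a fit of all 12 libraries (−0.38, adjusted p = 0.0237) and on log2(TPM + 1) (−0.55, adjusted p = 0.0297). Y-linked transcripts, taken as a measure of tumour RNA, stood at 36.9%, 0.184% and 7.08% of their NC level in OTUB1_KD replicates 1, 2 and 3, and at 0.0511% to 0.476% in SFD@M libraries. By this measure most RNA of these libraries came from other cells, so their Otub1 level cannot check a knockdown in tumour cells and neither backs nor contradicts the label. Directions are those of libraries named by their labels. Otub1 was lower in SFD@M than in Blank, at 47.0 ± 1.34 against 74.97 ± 2.66 CPM (−0.71 ± 0.05, adjusted p = 5.8e-06, lower in 3 of 3 libraries; exact permutation p = 0.1). The change of Otub1 did not differ between the experiments at the threshold (interaction 0.33 ± 0.19, adjusted p = 0.241). Mki67 was lower, and Ptprc and Sftpc higher, in both groups with the lower Otub1 means (adjusted p of 4.3e-09 to 0.0041).

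**Figure D2:**
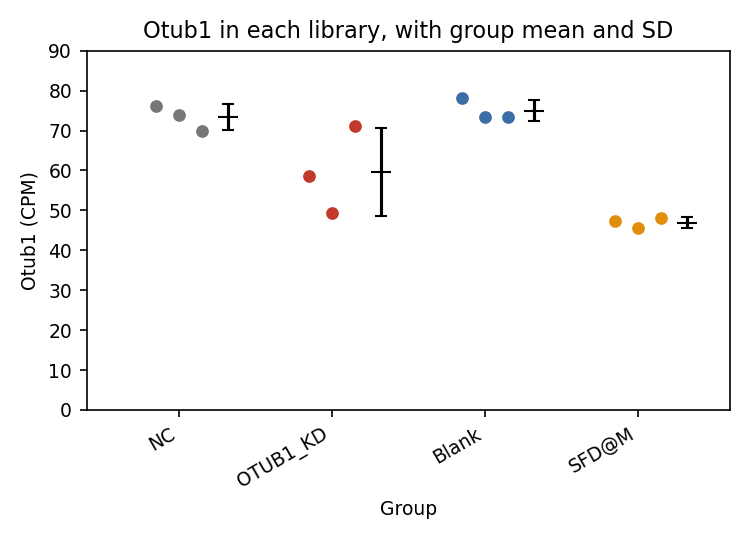
Otub1 in CPM (axis from 0) for each of the 12 libraries, with the mean and SD of each group of 3 beside its points. The SFD@M libraries lie at 45.5 to 48.1 CPM, below the Blank libraries at 73.3 to 78.0, and the libraries labelled OTUB1_KD spread from 49.3 to 71.2.

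By the labels, the comparison of OTUB1_KD with NC asks which transcripts differ in tumours grown from cells with the knockdown lentivirus. The 2 groups also differed in cell makeup, so the changes below cannot be assigned to the knockdown. Genes of the lung, vessels, blood and immune system were abundant in the libraries labelled OTUB1_KD and much lower in NC, many of them near 0. Of 123 markers of alveolar, endothelial, T, B and macrophage cells at 5 CPM or more in OTUB1_KD, 37 to 38 were at 1 CPM or more in NC libraries. Sftpc was at 12690 ± 5332 CPM after TMM scaling within the comparison (used below for levels beside a fold change), against 2 counts in the 3 NC libraries together, a ratio of 308400 (95% counting interval 85390 to 2547000). Scgb1a1 was at 18200 ± 8312 against 0.207 ± 0.129 CPM (log2 fold change 16.38 ± 0.77, adjusted p = 1.7e-05), and Hbb-bs, an adult beta-globin of red cells, at 4055 ± 1346 CPM against 2 counts (ratio 98540, interval 27280 to 813700). Mki67 fell from 714 ± 9.29 to 107 ± 83.8 CPM (−2.75 ± 0.54, adjusted p = 0.0041).

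Of 14785 genes tested, 9721 changed, 5903 higher and 3818 lower in OTUB1_KD (10291 at an unadjusted p under 0.05). Of these, 4875 higher and 2167 lower genes differed by at least 2-fold. In 79.2% of the genes tested the 3 libraries of a group lay wholly above or below those of the other, where chance gives 10%. The median change of all genes was 0.16. With limma on log2(TPM + 1) it moved to −0.09 and the calls to 4819 higher and 4888 lower, or 49.6% higher in place of 60.7%, so small shifts of gene lists are given below also relative to the median of all genes. Changes of single genes are not.

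The largest rises by the fixed rule were, besides Sftpc, Scgb1a1 and Hbb-bs, in 7 genes with 0 counts in NC. Sec14l3 was at least 18380-fold higher, Chil1, a chitinase-like protein, at least 13790-fold, Scgb3a2, an airway secretoglobin, at least 9584-fold, and Sftpd, surfactant protein D, at least 7915-fold. Ctsc, the protease that activates granule enzymes of leukocytes, was at least 7512-fold higher, Cdh5, the cadherin of endothelial junctions, at least 7014-fold, and Lamp3 at least 6010-fold. The largest falls were in genes of 3.27 to 20.3 CPM in NC. Ranbp3l (−7.34 ± 0.35), Lhfpl1 (−7.03 ± 0.42), the transcription factor genes Lhx9 (−6.74 ± 0.67) and Esrrb (−6.17 ± 0.47), and Tph1, which makes serotonin from tryptophan (−6.08 ± 0.78), fell with adjusted p of 1.7e-05 to 0.00061. Ces1a, Akr1cl and Cdk5r2 fell by 5.66, 5.55 and 5.36 on the log2 scale, and Ly6f and Cnnm1 had 3 counts each in OTUB1_KD, at 0.0055 (interval 0.0011 to 0.016) and 0.0170 (interval 0.0035 to 0.0505) of their NC levels.

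Immune genes rose together in the libraries labelled OTUB1_KD, in which Ptprc was also high. In antigen presentation by MHC class I, 20 of 23 measured genes rose and 2 fell, also adjusted over the list alone (median 2.04, camera adjusted p = 0.00015; adjusted p = 0.333 with an estimated correlation). Tap1, the peptide transporter, rose by 2.98 ± 0.15 and H2-K1, a class I heavy chain, by 3.34 ± 0.22, from 222 ± 5.16 to 2249 ± 380 CPM. All 12 measured MHC class II genes rose, and 12 adjusted over the list alone (median 6.69, camera adjusted p = 3.6e-05; adjusted p = 0.333 with an estimated correlation), with Ciita, their master regulator, up by 5.50 ± 0.25. Of 46 interferon-response genes 44 rose, and 44 adjusted over the list alone (median 3.67, camera adjusted p = 3.0e-10; adjusted p = 0.0579 with an estimated correlation). Gbp2, a guanylate-binding protein, went from 3.20 ± 0.58 to 725 ± 84.3 CPM (7.82 ± 0.27). T cell markers rose in 21 of 22 cases, also adjusted over the list alone (median 6.39, or 6.26 with members at their bound; camera adjusted p = 5.0e-08; adjusted p = 0.317 with an estimated correlation). Cd8a, the CD8 coreceptor, rose by 5.35 ± 0.28 to 30.5 ± 3.95 CPM.

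Among cytotoxic effector genes 16 of 17 rose, also adjusted over the list alone (median 8.56, or 7.06 with members at their bound; camera adjusted p = 3.4e-06; adjusted p = 0.176 with an estimated correlation). Gzmb, granzyme B, was at 16.3 ± 4.05 CPM against 1 count in NC, a ratio of 793 (interval 142 to 31340), and Ifng, interferon gamma, was at least 44.7-fold higher (149 against 0 counts). Macrophage markers rose in 27 of 31 cases and fell in 2, also adjusted over the list alone (median 8.59, or 7.24 with members at their bound; camera adjusted p = 4.0e-07; adjusted p = 0.333 with an estimated correlation). Csf1r, the receptor for macrophage growth factor, rose by 10.75 ± 0.32. Cd274, which encodes the checkpoint ligand PD-L1, rose by 2.44 ± 0.20 to 72.5 ± 13.7 CPM (adjusted p = 9.0e-05). The B cell and plasma cell list held 18 members that rose and 1 that fell of 19, also adjusted over the list alone (median 6.04, or 5.38 with members at their bound; camera adjusted p = 5.3e-06; adjusted p = 0.333 with an estimated correlation).

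Markers of resident lung cells moved with the immune genes. All 28 endothelial markers rose, also adjusted over the list alone (median 10.24, or 9.52 with members at their bound; camera adjusted p = 1.4e-09; adjusted p = 0.358 with an estimated correlation), Flt1, a VEGF receptor, by 5.50 ± 0.22. Alveolar epithelial markers rose in 25 of 26 cases, also adjusted over the list alone (median 9.30, or 8.67 with members at their bound; camera adjusted p = 6.6e-09; adjusted p = 0.355 with an estimated correlation). Airway epithelial markers rose in 25 of 26 cases, also adjusted over the list alone (median 10.34, or 8.79 with members at their bound; camera adjusted p = 3.4e-07; adjusted p = 0.358 with an estimated correlation). Cyp2f2, a cytochrome of club cells, rose from 0.453 ± 0.092 to 1424 ± 627 CPM. Fibroblast markers rose in 21 of 25 cases and fell in 2, also adjusted over the list alone (median 6.30, camera adjusted p = 2.1e-05; adjusted p = 0.264 with an estimated correlation), Col1a2, a collagen chain, by 6.30 ± 0.26.

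Genes of cell division fell where those markers rose. Of 39 mitosis genes 37 fell, and 37 adjusted over the list alone (median −2.16, camera adjusted p = 2.8e-09; adjusted p = 0.464 with an estimated correlation). Bub1b, a spindle checkpoint kinase, went from 231 ± 3.79 to 38.8 ± 23.2 CPM (−2.58 ± 0.45). Of 36 DNA replication genes 32 fell, and 34 adjusted over the list alone (median −1.71, camera adjusted p = 3.3e-08; adjusted p = 0.469 with an estimated correlation), among them the ribonucleotide reductase subunit Rrm1 (−1.82 ± 0.32) and the helicase subunit Mcm4 (−1.67 ± 0.31). In glycolysis and hypoxia 20 of 36 genes fell and 4 rose, with 22 and 4 adjusted over the list alone (median −1.20, camera adjusted p = 6.0e-05; adjusted p = 0.479 with an estimated correlation), where Ddit4 fell by 2.37 ± 0.44 and the fry test missed the threshold (adjusted p = 0.0681). Cytosolic ribosomal protein genes fell in 32 of 75 cases, and in 21 adjusted over the list alone (median −0.53, or −0.69 relative to all genes; camera adjusted p = 4.3e-07; adjusted p = 0.476 with an estimated correlation), Rpl5 by 1.08 ± 0.24.

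For ferroptosis, an iron-dependent death by lipid peroxidation, the panel fixed in advance moved in both directions. The lung and immune markers named above rose in the same libraries. Y-linked transcripts stood at 36.9%, 0.184% and 7.08% of their NC level in OTUB1_KD replicates 1, 2 and 3. Changes of the panel in tumour cells therefore cannot be told apart from the change in cell makeup. Tfrc, the transferrin receptor, fell from 292 ± 2.64 to 83.7 ± 5.55 CPM (−1.80 ± 0.15, adjusted p = 8.9e-05). Ptgs2, cyclooxygenase 2, fell from 110 ± 3.38 to 28.2 ± 11.6 CPM (−1.96 ± 0.29, adjusted p = 0.0011). Hmox1, heme oxygenase 1, rose from 33.3 ± 2.27 to 239 ± 198 CPM (2.85 ± 0.73, adjusted p = 0.012). The lipid peroxide reductase gene Gpx4 (0.35 ± 0.20, adjusted p = 0.170), the cystine transporter gene Slc7a11 (−0.45 ± 0.41, adjusted p = 0.359), Acsl4, which loads membranes with polyunsaturated fat (0.40 ± 0.29, adjusted p = 0.255), Fth1, ferritin heavy chain (−0.20 ± 0.26, adjusted p = 0.518), and Aifm2, which encodes FSP1 (0.21 ± 0.15, adjusted p = 0.259), did not pass the test. Without OTUB1_KD replicate 1, Gpx4 passed at 0.49 (adjusted p = 0.0137), and without replicate 3, Acsl4 passed at 0.66 (adjusted p = 0.0099). Of 30 ferroptosis suppressors 10 rose and 4 fell, also adjusted over the list alone (median 0.10, or −0.06 relative to all genes; camera adjusted p = 0.849; adjusted p = 0.852 with an estimated correlation), with a median above 0 while the test pointed down; on log2(TPM + 1) the median was −0.0094. Of 32 ferroptosis drivers 14 rose and 5 fell, also adjusted over the list alone (median 0.33, or 0.17 relative to all genes; camera adjusted p = 0.508; adjusted p = 0.583 with an estimated correlation).

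In the ubiquitin system, 13 of 29 ubiquitin-specific proteases fell and 2 rose, also adjusted over the list alone (median −0.47, or −0.63 relative to all genes; camera adjusted p = 0.0022; adjusted p = 0.333 with an estimated correlation), Usp10 by 1.09 ± 0.23 on the log2 scale. Among 31 proteasome subunits 6 fell and 3 rose, and 0 either way adjusted over the list alone (median −0.26, or −0.42 relative to all genes; camera adjusted p = 0.0447; adjusted p = 0.640 with an estimated correlation). Of 25 OTUB1 substrates and partners taken from the literature 10 fell and 3 rose, with 9 and 3 adjusted over the list alone (median −0.28, or −0.44 relative to all genes; camera adjusted p = 0.0477; adjusted p = 0.469 with an estimated correlation), among them Ube2n, the conjugating enzyme that OTUB1 binds (−0.84 ± 0.19). The proteasome and partner lists both lost their call without OTUB1_KD replicate 2 (adjusted p = 0.0917 and 0.0544), by ranks (0.0918 and 0.0698) and by fry (0.243 and 0.201). The lung and immune markers named above rose in the same libraries.

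Of 50 lists tested, camera called 31, with 24 higher and 7 lower; 0 were called with an estimated correlation, 29 by ranks and 43 by the fry test. Other divisions of these 6 libraries into 3 and 3 called up to 31 lists, so a list call carries little weight of its own beside the single-gene counts.

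By the labels, the comparison of SFD@M with Blank asks which transcripts differ in tumours of treated mice. Y-linked transcripts, taken as a measure of tumour RNA, stood at 0.0511% to 0.476% of their NC level in SFD@M libraries. By that measure the changes below set libraries with little tumour RNA against controls poor in host transcripts. Lung and immune genes were again abundant in the treated libraries and much lower in the controls, where 28 to 31 of 108 such markers were at 1 CPM or more, and genes of cell division were lower. Pecam1, the endothelial adhesion molecule CD31, went from 0.825 ± 0.115 to 797 ± 95.7 CPM (log2 fold change 9.90 ± 0.16, adjusted p = 5.6e-09) and Scgb1a1 from 0.137 ± 0.123 to 31850 ± 1320 CPM (17.75 ± 0.29). Mcm6, a subunit of the replicative helicase, fell from 528 ± 8.56 to 34.6 ± 0.485 CPM (−3.93 ± 0.05, adjusted p = 4.3e-09), and Mad2l1, a spindle checkpoint gene, from 446 ± 14.8 to 10.6 ± 0.625 CPM (−5.40 ± 0.07).

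Of 14824 genes tested, 13062 changed, 7331 higher and 5731 lower in SFD@M (13114 at an unadjusted p under 0.05), and 5469 higher and 3035 lower genes differed by at least 2-fold. The 3 libraries of a group lay wholly above or below the other 3 in 90.1% of genes, where chance gives 10%. The median change of all genes was 0.23. On log2(TPM + 1) it was −0.13, with 5839 higher and 6661 lower calls, or 46.7% higher in place of 56.1%.

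By the fixed rule the largest rises were in Sftpa1, surfactant protein A (at least 70830-fold higher, 0 counts in Blank), Timp3, an inhibitor of metalloproteases (at least 27410-fold), Cd36, a fatty acid receptor (at least 22890-fold), and Hpgd, which degrades prostaglandins (at least 19900-fold). Sftpd, Scgb3a2, Chil1 and the neutrophil gene S100a9 were at least 16000-fold, 14180-fold, 12940-fold and 11670-fold higher. Sftpc and Scgb1a1 completed the 10. The largest falls included 2 genes of the Y chromosome, Eif2s3y (from 135 ± 6.63 to 0.0959 ± 0.166 CPM, −10.34 ± 0.31) and Kdm5d (1 against 2639 counts, a ratio of 0.00037 with a 95% counting interval of 9.5e-06 to 0.0021). They also included the reproductive homeobox genes Rhox2d (1 against 4792 counts, ratio 0.00021, interval 5.2e-06 to 0.0011) and Rhox2h (−10.15 ± 0.30). The developmental transcription factor genes Pax3 and Dlx2 had 1 count each in SFD@M against 1619 and 1340 in Blank (ratios 0.00061, interval 1.5e-05 to 0.0034, and 0.00074, interval 1.9e-05 to 0.0041), and Zic2 was at least 259-fold lower. The channel gene Trpa1 (1 against 2100 counts, ratio 0.00047, interval 1.2e-05 to 0.0026), Gpr149 (3 against 3027 counts, ratio 0.00098, interval 0.0002 to 0.0029) and Pramel34 (at least 124-fold lower) were the others. Rhox2d, Rhox2h and Pramel34 belong to families of near-identical copies among which the deposited counts could divide reads.

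Immune genes rose in the SFD@M libraries, which also held lung and endothelial markers. MHC class I genes rose in 20 of 23 cases and fell in 3, also adjusted over the list alone (median 1.27, camera adjusted p = 0.0064; adjusted p = 0.487 with an estimated correlation), H2-K1 by 3.33 ± 0.11 and the nonclassical gene H2-T23 by 4.71 ± 0.07. MHC class II genes rose in 11 of 12 cases, also adjusted over the list alone (median 6.77, or 6.26 with members at their bound; camera adjusted p = 0.0017; adjusted p = 0.292 with an estimated correlation). Of 46 interferon-response genes 36 rose and 2 fell, also adjusted over the list alone (median 2.65, camera adjusted p = 0.00051; adjusted p = 0.478 with an estimated correlation), Ifit3 by 5.76 ± 0.19. T cell markers rose in 21 of 22 cases, also adjusted over the list alone (median 6.26, or 5.91 with members at their bound; camera adjusted p = 5.0e-05; adjusted p = 0.351 with an estimated correlation), Cd8a from 0.197 ± 0.090 to 12.6 ± 1.17 CPM. Gzmb was at least 260-fold higher (792 against 0 counts). Ifng was too low to be tested, with 28 counts in the 3 SFD@M libraries and 0 in Blank. Cd274 rose from 9.54 ± 0.264 to 25.3 ± 3.41 CPM (1.403 ± 0.12, adjusted p = 1.2e-05).

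Macrophage markers rose in 29 of 31 cases and fell in 2, also adjusted over the list alone (median 8.70, or 7.82 with members at their bound; camera adjusted p = 4.9e-06; adjusted p = 0.219 with an estimated correlation), Lyz2, a lysozyme, by 10.83 ± 0.15 to 4443 ± 280 CPM. Neutrophil and granulocytic markers rose in 25 of 26 cases, also adjusted over the list alone (median 8.67, or 8.47 with members at their bound; camera adjusted p = 3.8e-05; adjusted p = 0.351 with an estimated correlation), among them Mmp9, a gelatinase (6.23 ± 0.21). All 28 endothelial markers rose, also adjusted over the list alone (median 12.45, or 10.26 with members at their bound; camera adjusted p = 5.0e-08; adjusted p = 0.292 with an estimated correlation). So did 26 of 26 alveolar epithelial markers, also adjusted over the list alone (median 10.20, or 10.06 with members at their bound; camera adjusted p = 8.1e-08; adjusted p = 0.266 with an estimated correlation). Napsa, the aspartic protease of surfactant processing, rose by 7.90 ± 0.08.

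All 39 mitosis genes and all 36 DNA replication genes fell, and as many adjusted over the list alone, in the libraries with the lung and immune markers. Their medians were −5.28 (camera adjusted p = 2.1e-09; adjusted p = 0.430 with an estimated correlation) and −4.01 (camera adjusted p = 5.0e-12; adjusted p = 0.266 with an estimated correlation). Glycolysis and hypoxia genes fell in 26 of 36 cases and rose in 6, also adjusted over the list alone (median −2.05, camera adjusted p = 3.6e-05; adjusted p = 0.254 with an estimated correlation), Pgk1, a glycolytic kinase, by 3.85 ± 0.08 and Hk2, hexokinase 2, by 3.02 ± 0.05. In the unfolded protein and integrated stress response 22 of 34 genes fell and 8 rose, also adjusted over the list alone (median −0.96, camera adjusted p = 0.012; adjusted p = 0.478 with an estimated correlation). Those with the smallest p make serine and asparagine, namely Phgdh (−6.74 ± 0.07), Psat1 (−4.36 ± 0.06) and Asns (−3.69 ± 0.05). Cytosolic ribosomal protein genes fell in 61 of 75 cases and rose in 2, also adjusted over the list alone (median −0.71, or −0.94 relative to all genes; camera adjusted p = 8.1e-08; adjusted p = 0.502 with an estimated correlation), Rps2 by 2.64 ± 0.09.

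The SFD@M libraries held high lung and immune markers, and their Y-linked transcripts stood at 0.0511% to 0.476% of the NC level. Changes of the ferroptosis panel in tumour cells therefore cannot be told apart from the change in cell makeup. In the panel, Slc7a11 fell from 151 ± 7.70 to 24.0 ± 5.05 CPM (−2.65 ± 0.15, adjusted p = 1.2e-06). Tfrc fell from 527 ± 4.12 to 111 ± 21.1 CPM (−2.25 ± 0.13, adjusted p = 1.5e-06). Fth1 (−0.51 ± 0.08, adjusted p = 0.00049) and Ptgs2 (−0.97 ± 0.17, adjusted p = 0.00091) fell, while Acsl4 (0.76 ± 0.11, adjusted p = 0.00026), Hmox1 (1.04 ± 0.13, adjusted p = 0.00015) and Aifm2 (0.64 ± 0.11, adjusted p = 0.00071) rose. Gpx4 rose by 0.48 ± 0.11 (adjusted p = 0.0045), a call that ended on log2(TPM + 1), at 0.18 (adjusted p = 0.147). Of 30 ferroptosis suppressors 14 rose and 15 fell, also adjusted over the list alone (median −0.09, or −0.33 relative to all genes; camera adjusted p = 0.536; adjusted p = 0.597 with an estimated correlation), with a mean of 0.34 and a median of 0.0024 on log2(FPKM + 1). Of 33 drivers 19 rose and 10 fell, also adjusted over the list alone (median 0.42, or 0.19 relative to all genes; camera adjusted p = 0.536; adjusted p = 0.545 with an estimated correlation).

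In the ubiquitin system, proteasome subunits fell in 29 of 31 cases and rose in 1, also adjusted over the list alone (median −1.07, camera adjusted p = 1.5e-07; adjusted p = 0.266 with an estimated correlation), Psma5 by 2.06 ± 0.05. Ubiquitin-specific proteases fell in 21 of 29 cases and rose in 4, also adjusted over the list alone (median −0.53, or −0.76 relative to all genes; camera adjusted p = 0.0013; adjusted p = 0.219 with an estimated correlation), Uchl5, a proteasome-bound deubiquitinase, by 2.22 ± 0.07. Of the 25 OTUB1 substrates and partners 15 fell and 6 rose, also adjusted over the list alone (median −0.33, or −0.56 relative to all genes; camera adjusted p = 0.034; adjusted p = 0.292 with an estimated correlation), Trp53, which encodes p53, by 1.66 ± 0.05. Ptprc, Sftpc and Pecam1 were high in the same libraries.

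Of 50 lists tested, camera called 33, with 24 higher and 9 lower; 0 were called with an estimated correlation, 33 by ranks and 49 by the fry test. Other divisions of the 6 libraries called up to 32 lists.

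**Figure D3:**
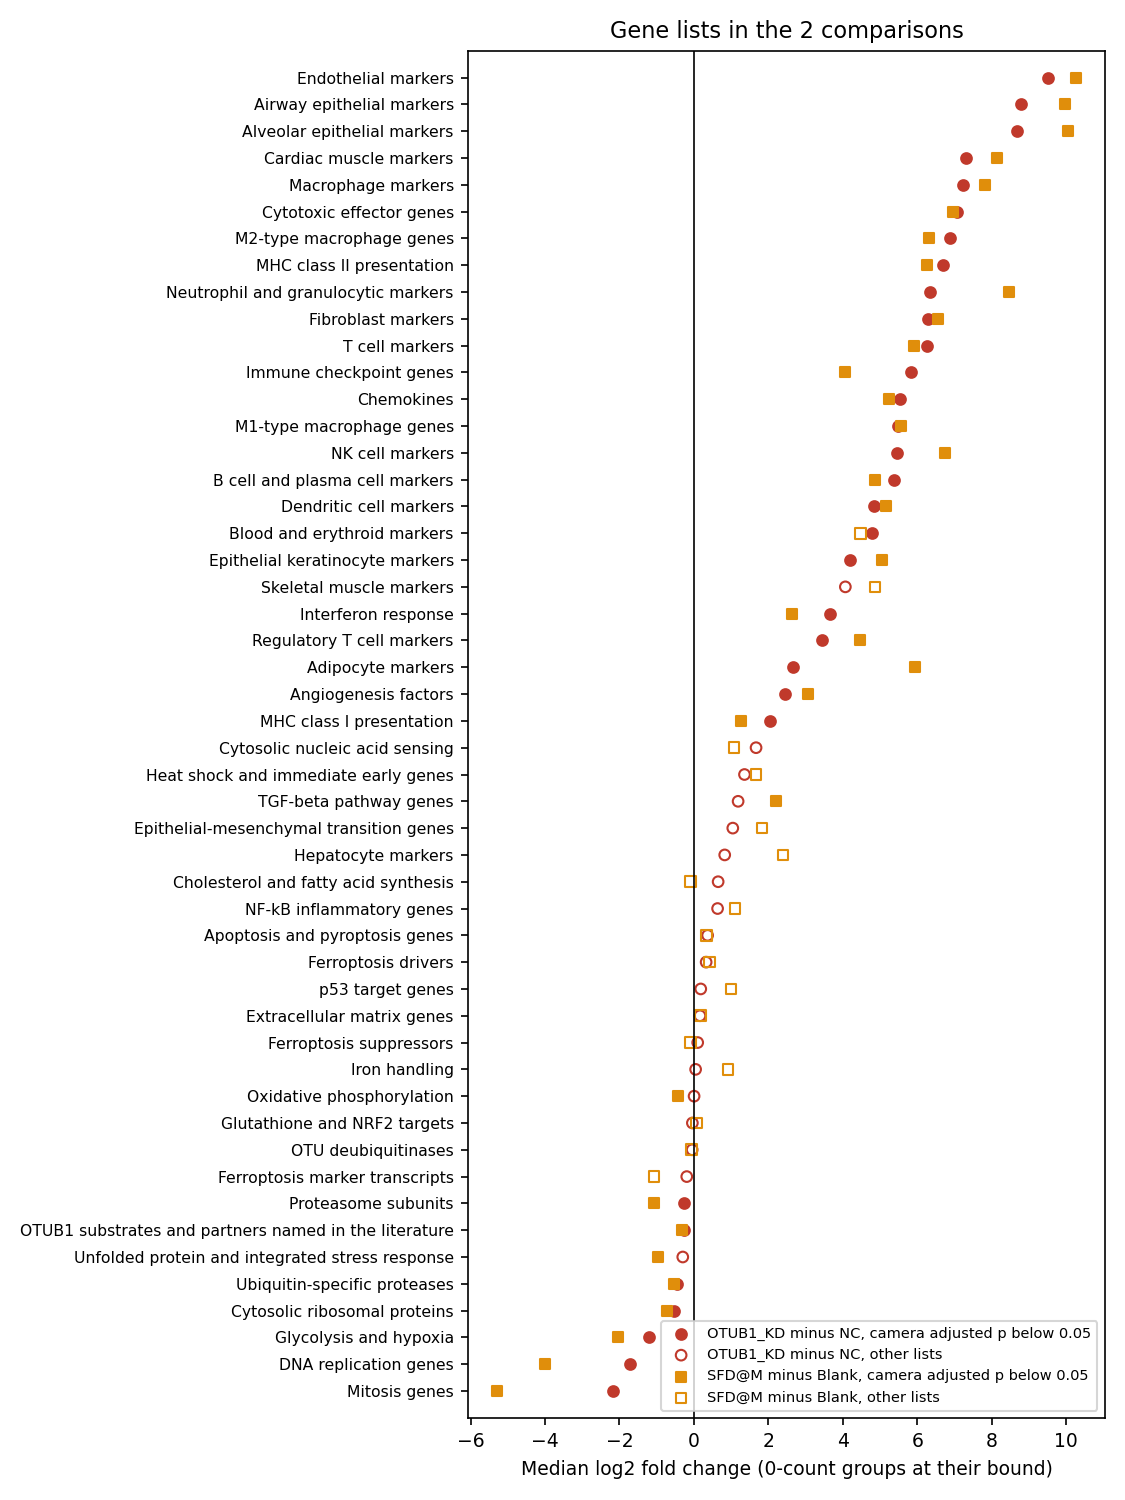
Median log2 fold change of the tested members of each of 50 gene lists, with members that have 0 counts in a group at their bound, for OTUB1_KD minus NC (circles) and SFD@M minus Blank (squares), filled where the camera adjusted p is below 0.05, a call that no list keeps with an estimated correlation. Endothelial, airway and alveolar markers lie highest in both comparisons and mitosis and DNA replication genes lowest, and medians within 0.2 of 0 can change sign with the scaling.

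Set against each other, the comparisons had much in common. Over 14504 genes tested in both, which share no control library, their log2 fold changes correlated across genes at Pearson r = 0.951 and Spearman rho = 0.923. Of 9021 genes called in both, 98.4% had the same sign and 142 the opposite sign. Both called 5473 genes higher, where independent lists would share 2811, and 3406 lower, where they would share 1472. Both comparisons set libraries rich in lung and immune transcripts against controls poor in them, and NC and Blank libraries correlated at r = 0.990. The likeness of the comparisons therefore cannot be told apart from this shared contrast in cell makeup. It does not show that SFD@M acted like the knockdown. The test of the difference between the changes found 3537 of 15304 genes (5638 at an unadjusted p under 0.05), 1646 more positive in OTUB1_KD against NC and 1891 more positive in SFD@M against Blank. The count fell to 2090 to 2135 without any 1 NC or Blank library and to 2319 without SFD@M replicate 2, and rose to 5523 without OTUB1_KD replicate 2. The fit takes 1 spread per gene over all 4 groups, which vary unequally. Counts differed by 96.9 to 160 times the sampling variance within OTUB1_KD and by 1.32 to 2.00 times within NC and Blank. Errors for OTUB1_KD may therefore be too small and the count too high.

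Cdkn1a, which encodes the cell-cycle inhibitor p21, and Fam107a, an actin-associated stress gene, differed most by p. Cdkn1a had a log2 fold change of 1.77 in OTUB1_KD against NC and 5.49 in SFD@M against Blank (difference −3.75 ± 0.18, adjusted p = 2.0e-06), and Fam107a had 0.08 and 6.95 (difference −6.91 ± 0.32, adjusted p = 2.0e-06). Slc7a11, at −0.45 and −2.65, differed by 2.19 ± 0.49 (adjusted p = 0.011), and Cd274, at 2.44 and 1.403, by 1.02 ± 0.23 (adjusted p = 0.012). These differences also hold the difference between the control groups NC and Blank. SFD@M minus OTUB1_KD alone was 2.17 for Cdkn1a and 3.33 for Fam107a. It was −1.66 for Slc7a11 and −1.53 for Cd274, neither called by edgeR (adjusted p = 0.117 and 0.0689). Blank minus NC was 0.58 for Slc7a11 and −0.47 for Cd274. Ptprc and Sftpc were high in both OTUB1_KD and SFD@M libraries, but not every host marker was. In CPM of library totals, Hbb-bs stood at 4132 ± 1297 in OTUB1_KD and at 94.0, 0.707 and 0.617 CPM in SFD@M replicates 1, 2 and 3, and S100a9 at 145 ± 90.5 and 696 ± 174 CPM.

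**Figure D4:**
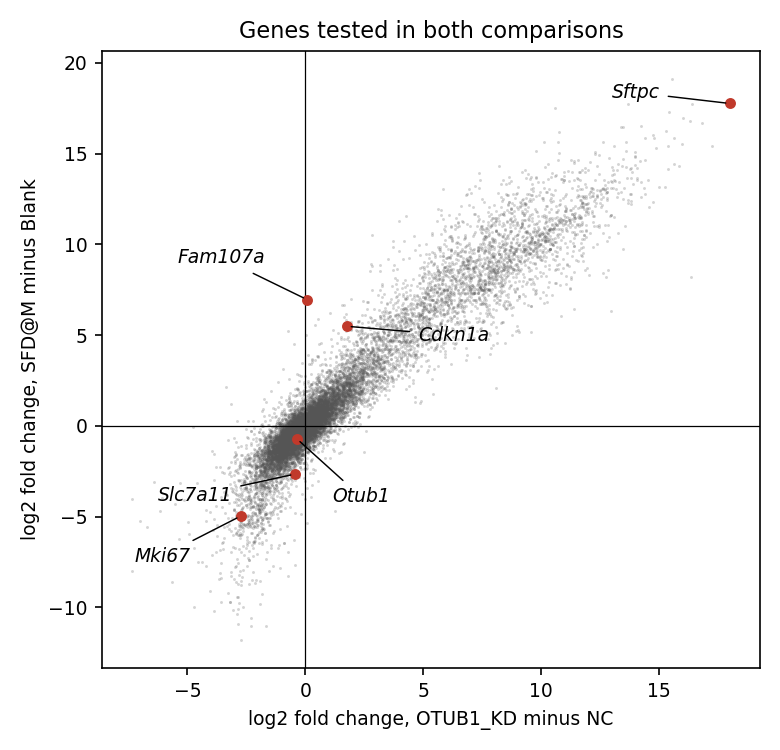
Each point is 1 of the 14504 genes tested in both comparisons, with its log2 fold change for OTUB1_KD minus NC across and SFD@M minus Blank upward. The points follow a rising band (Pearson r = 0.951), from which Cdkn1a and Fam107a lie above and near whose centre Otub1 lies.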

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

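The weighing of the cell makeup of the libraries and of dilution by tumour RNA, and the test of p53 targets, were chosen after the results were seen; the tests of the Y-linked transcripts and of the glucocorticoid-induced genes were written before their results.

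The change from NC to OTUB1_KD differed from the change from Blank to SFD@M, by the interaction test, in 3537 genes. That test takes 1 spread over groups that vary unequally, and its differences also hold any difference between NC and Blank. Fam107a (−6.91), Selenbp2, a selenium-binding protein (−4.17), Cdkn1a (−3.75), Enpp2, which makes lysophosphatidic acid (−3.44), and the glycosyltransferase gene A4galt (−3.31) were more positive in the treatment experiment. Apol9b (2.80), Tmco4 (2.30), Cdkn2c, an inhibitor of cyclin-dependent kinases (1.55), Ufc1, the conjugating enzyme of the ubiquitin-like protein UFM1 (1.48), and the adenylate cyclase gene Adcy7 (1.296) were more positive in the knockdown experiment. Of the 13 panel genes, Slc7a11 (2.19) and Cd274 (1.02) differed. Among the largest falls and rises, Ranbp3l differed by −3.33, Cd36 by −6.92, Rhox2d by 9.04, Zic2 by 9.30, Kdm5d by 8.06, Trpa1 by 8.26, Eif2s3y by 7.43, Pax3 by 6.31, Rhox2h by 7.05, Pramel34 by 5.2, Dlx2 by 7.30 and Gpr149 by 7.90. These last values rest on groups with few or 0 counts, in which a fitted change depends on the prior count, and are no bounds. Eif2s3y and Kdm5d are among the Y-linked genes taken below as a measure of tumour RNA, and Rhox2d and Rhox2h among the 15 other genes set beside them. Eif2s3y stood at 46.5, 0.0578 and 9.21 CPM of library totals in OTUB1_KD replicates 1, 2 and 3. For these genes a differing change cannot be told apart from a differing share of tumour RNA. Of 190 other named members of the gene lists 61 differed, 35 more positive in the knockdown experiment and 26 in the treatment experiment. In 100 divisions of the libraries the real one gave the largest count (1 of 100; 3537 against 3 at most elsewhere). The other divisions mix groups, which raised the common dispersion from 0.0491 to between 0.549 and 1.17, so their low counts were set by the differences between groups and do not exclude chance division.

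Most host transcripts were far lower in the NC and Blank libraries, though 37 to 38 of 123 host markers in NC and 28 to 31 of 108 in Blank were at 1 CPM or more, and 71 to 77 and 73 to 76 lay under 1% of the partner group. The median of these markers, which were picked as abundant in the partner group, stood at 0.282% to 0.358% of the OTUB1_KD level in NC libraries and at 0.0271% to 0.0653% of the SFD@M level in Blank libraries; the highest, 0.358%, restates the pattern, so control samples of tumour cells with almost no host cells, such as cultured cells, cannot be told apart from other sources of low host RNA. Entry of immune cells into the tumours cannot be the whole cause, since alveolar markers held by no other list, with controls at no less than 3 counts, had median log2 ratios of 8.57 and 10.06, with 24 of 25 above 1 in each comparison. The titles of the Blank samples carry codes that begin with KD. An exchange of the labels OTUB1_KD and Blank, with a knockdown that lowers Otub1 mRNA, would put Otub1 lower in Blank than in NC. The Otub1 difference between Blank and NC was 0.0314 ± 0.0386, which argues against such an exchange. That error comes from libraries that cannot be told apart from technical repeats, so it need not hold for separate samples. Judged by makeup alone, an exchange cannot be told apart from control samples without host tissue. The NC libraries resembled Blank (r = 0.990) more than OTUB1_KD (at most 0.848), and both readings give that order. The changes of the report may therefore compare tissue with tumour cells as much as knockdown or treatment with control, and what knockdown or SFD@M did to tumour cells stays open.

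Y-linked transcripts spread widely within OTUB1_KD, with Ddx3y, a Y-linked helicase, at 18.6 ± 25.8 CPM (of library totals) against 125 ± 2.67 in NC and 0.157 ± 0.222 in SFD@M. Relative to NC, the Y-linked genes gave shares of 36.9%, 0.184% and 7.08% in replicates 1, 2 and 3, and 15 other genes, abundant in NC and Blank and under 1 CPM in SFD@M, gave 34.5%, 0.118% and 10.1%. The largest gap between these shares where the Y-linked share was at least 1% was 1.43-fold, which is consistent with a share of RNA from Y-bearing tumour cells that differs between the libraries. Male host animals are excluded as the whole cause, since the other genes differed 293-fold between the same libraries. In the SFD@M libraries the Y-linked share was 0.0511% to 0.476%, and the other genes, picked as low there, give no second measure; falls of proliferation genes may follow the share of tumour RNA; a lower share of tumour cells brought about by knockdown or treatment was not tested.

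Cdkn1a and Fam107a were higher in SFD@M than in OTUB1_KD libraries, 4.49-fold and 10.0-fold; dilution of the OTUB1_KD libraries by tumour RNA allows at most 1.58-fold, below the folds taken 2 standard errors lower (3.42 and 7.06), and is excluded as the whole cause. The p53 targets without Cdkn1a had a median log2 fold change of 0.65 (23 of 29 positive; 0 passed over all genes, 13 rose and 2 fell adjusted over the list alone; camera unadjusted p = 1.1e-06, unadjusted p = 0.0054 with an estimated correlation; 8 are in other lists), which lies just within that limit, itself set by the highest tumour share for all 3 libraries, while 6 of 29, against 0.999% of all genes, exceed it by more than 2 standard errors. The list as fixed, tested beside the other lists, lost its call with an estimated correlation (adjusted p = 0.196), so a p53 programme stays open. Glucocorticoid-induced genes had a median of 0.99 (12 of 15 positive, 3 above the limit likewise; 0 passed over all genes, 8 rose adjusted over the list alone; camera unadjusted p = 4.2e-06, unadjusted p = 0.012 with an estimated correlation; 2 are in other lists). Either programme may take part, as a hypothesis; the groups come from separate experiments, so batch, host tissue sampled and treatment are confounded.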

How the results depend on the processing

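Scalings by recovered whole reads, the panel genes on log2(TPM + 1) and the comparisons of Blank with NC and SFD@M with OTUB1_KD were added after the data were seen; the other alternatives were planned. Values that answer a comparison are mostly counts of genes or lists, which were compared by size with the main count. The correlation and the ratios of Otub1 were compared by size too, and the tests of Otub1 by sign and side of the threshold. Of these values 275 counted as the same under an alternative, 37 as weaker, 23 as stronger, 1 as moved and 0 as reversed. Of single genes and lists, judged by sign and side of the threshold, 4606 stayed, 192 became weaker, 12 stronger and 10 reversed. At a 2-fold minimum 2167 genes were lower in OTUB1_KD, and 8504 changed in SFD@M, 3035 of them lower, by construction. With an estimated correlation 0 lists were called in each comparison, while fry called 40 between Blank and NC and 12 between SFD@M and OTUB1_KD. Otub1 in OTUB1_KD passed the threshold in the fit of all 12 libraries (−0.38), on log2(TPM + 1) (−0.55) and on log2(TPM + 0.1) (−0.56). Its log2 ratio of SFD@M to Blank was −0.99 in deposited TPM. The top transcript of a library took 23.32% to 23.84% of TPM in SFD@M and 8.814% to 19.54% in OTUB1_KD. In NC and Blank the top transcript took 1.298% to 1.541%. TPM is a share, so a larger top transcript lowers the TPM of other genes in SFD@M and OTUB1_KD. How much of the TPM shifts this makes was not computed. The fit of all 12 libraries takes 1 spread over groups that vary unequally, and whether this made Otub1 pass was not tested. Between SFD@M and OTUB1_KD, DESeq2 called 1426 genes (478 higher, 948 lower), limma-voom 7 (4 and 3) and the test without a filter 15 (6 and 9), against 2, and the cause was not tested. Gpx4 there turned sign at 0.00042 with DESeq2 size factors, 0.0025 with DESeq2, 0.0268 on log2(TPM + 1) and 0.0805 on log2(FPKM + 1).

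With each library left out in turn, Otub1 ranged from −0.53 (without OTUB1_KD replicate 3) to −0.24 (without replicate 2) in OTUB1_KD against NC, and from −0.0042 to 0.0595 between Blank and NC. Changed genes ranged from 7991 to 11141 in OTUB1_KD and 12776 to 13324 in SFD@M, and the correlation between the experiments from 0.940 to 0.956. The count between SFD@M and OTUB1_KD went from 0 to 1875 (higher 0 to 544, lower 0 to 1331), with 1875 without OTUB1_KD replicate 2. The interaction count went from 2090 to 5523 (more positive in OTUB1_KD 866 to 2882, in SFD@M 1183 to 2702), lowest without NC replicate 1 and highest without OTUB1_KD replicate 2. Sign-changing ranges between SFD@M and OTUB1_KD were −0.16 to 0.16 for Gpx4, −0.35 to 0.25 for Ptgs2 and −0.35 to 0.19 for Gzmb. The cause of these ranges was not tested.

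The replicate numbers do not pair the libraries by the labels, and same-numbered libraries deviated together at −0.0023 to 0.0572; in the treatment experiment each correlated best with its own number, a hint only. With the replicate number as a block 9362 genes changed in OTUB1_KD and 13010 in SFD@M, and 1006 were more positive in OTUB1_KD in the interaction. Depth of 16062806 to 18028828 counts per library leaves genes such as Ifng in Blank without a measurable level.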

Other observations

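The comparisons of Blank with NC and of SFD@M with OTUB1_KD, and their tests, were chosen after the makeup of the libraries had been seen; the counts over other divisions of the libraries were planned.

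The control groups of the 2 experiments, both poor in host transcripts, differed from each other. They belong to separate experiments, so batch and any other difference between the experiments are confounded here. Libraries within NC and within Blank (r = 0.999) cannot be told apart from technical repeats. The p-values, errors and lack of overlap given here may therefore measure technical spread alone, and small differences need not hold for separate samples. Several chemokine genes and the complement gene C3 were lower in Blank than in NC. The neutrophil-attracting chemokine gene Cxcl5 stood at 1.76 ± 0.223 against 302 ± 7.15 CPM (log2 fold change −7.42 ± 0.06), Cxcl1 at 11.1 ± 0.887 against 130 ± 1.74 (−3.55 ± 0.05) and C3, complement component 3, at 5.08 ± 0.488 against 133 ± 4.13 (−4.71 ± 0.06). Of 14 chemokines 12 fell, also adjusted over the list alone (median −2.74, camera adjusted p = 7.1e-06; adjusted p = 0.108 with an estimated correlation). In NC and Blank libraries Ptprc stood at 0 to 3 counts and S100a9 at 0, so myeloid lists cannot measure myeloid cells there. The members of these lists that could be tested were mostly lower in Blank too, also adjusted over each list alone. Of these, 6 of 6 tested neutrophil markers fell (median −2.66, camera adjusted p = 0.0072; adjusted p = 0.108 with an estimated correlation), 7 of 8 M1-type macrophage genes, which share Ccl5 and Cxcl10 with the chemokines (median −1.31, camera adjusted p = 0.002; adjusted p = 0.108 with an estimated correlation), and 9 of 12 macrophage markers, of which 2 rose (median −0.76, camera adjusted p = 0.0452; adjusted p = 0.166 with an estimated correlation). The macrophage call ended without NC replicate 2 or 3 or Blank replicate 3 (adjusted p = 0.0712, 0.0778 and 0.061). Interferon-response genes went the other way, with 26 of 41 higher in Blank and 6 lower, also adjusted over the list alone (median 0.38, camera adjusted p = 0.0049; adjusted p = 0.132 with an estimated correlation). Atf4, the transcription factor of the integrated stress response, was higher in Blank, at 607 ± 12.8 against 243 ± 7.58 CPM (1.32 ± 0.03), with its target Trib3 (1.64 ± 0.06). In the unfolded protein and integrated stress response 26 of 33 genes rose and 4 fell, also adjusted over the list alone (median 0.49, camera adjusted p = 5.1e-06; adjusted p = 0.108 with an estimated correlation). Genes of cholesterol and fatty acid synthesis rose in 26 of 32 cases and fell in 1, also adjusted over the list alone (median 0.49, camera adjusted p = 1.7e-06; adjusted p = 0.0889 with an estimated correlation), Scd2, a fatty acid desaturase, by 1.27 ± 0.02. Proteasome subunits rose in 30 of 31 cases and fell in 1, also adjusted over the list alone (median 0.56, camera adjusted p = 1.6e-09; adjusted p = 0.108 with an estimated correlation). Of the ferroptosis panel, Ptgs2 (−1.105 ± 0.04), Aifm2 (−0.76 ± 0.07), Hmox1 (−0.27 ± 0.06) and Fth1 (−0.09 ± 0.02) were lower in Blank, and Tfrc (0.87 ± 0.02) and Slc7a11 (0.58 ± 0.03) higher. Gpx4 (−0.12 ± 0.04, adjusted p = 0.0233) lost its call on log2(TPM + 1) (adjusted p = 0.191) and without NC replicate 3 or Blank replicate 1 or 2 (0.0508, 0.0788 and 0.0763). Acsl4 (0.07 ± 0.03, adjusted p = 0.0284) lost it with upper-quartile factors (0.218), on log2(FPKM + 1) (0.0738), with DESeq2 (0.0835) and without NC replicate 2 or 3 or Blank replicate 2 (0.0953, 0.0599 and 0.123). In all 8977 of 12087 genes differed, 4477 higher and 4500 lower, but at least 2-fold only in 175 and 894, and the groups did not overlap in 75.3% of genes, where chance gives 10%.

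SFD@M and OTUB1_KD libraries differed in 2 genes by edgeR, Fam107a (72.6 ± 12.9 against 7.23 ± 1.73 CPM, 3.33 ± 0.25, adjusted p = 0.019) and Cdkn1a (364 ± 24.1 against 81.0 ± 11.5 CPM, 2.17 ± 0.20, adjusted p = 0.033), with 2966 of 14914 at an unadjusted p under 0.05. Fam107a lost its call without OTUB1_KD replicate 3 (adjusted p = 0.123) or SFD@M replicate 2 or 3 (0.155 and 0.0609), and Cdkn1a without OTUB1_KD replicate 3 (0.123) or any 1 SFD@M library (0.0828 to 0.196), with log2 fold changes of 3.15 to 3.35 and 2.14 to 2.27 in these fits. DESeq2 called 1426 genes and limma-voom 7. The groups did not overlap in 28.1% of genes, where chance gives 10%. The edgeR count was 1875 without OTUB1_KD replicate 2, which held the least tumour RNA, 7 without replicate 1 and 0 without replicate 3, and 6, 0 and 0 without SFD@M replicates 1, 2 and 3. As a list, mitosis genes were lower in SFD@M, 0 over all genes and 38 of 39 adjusted over the list alone (median −2.79, camera adjusted p = 1.2e-22; adjusted p = 0.378 with an estimated correlation; fry adjusted p = 0.0798). Y-linked transcripts stood at 36.9%, 0.184% and 7.08% of their NC level in OTUB1_KD replicates 1, 2 and 3 and at most 0.476% in SFD@M. MHC class II genes were lower likewise, 0 over all genes and 12 of 12 adjusted over the list alone (median −1.64, camera adjusted p = 1.3e-10; adjusted p = 0.378 with an estimated correlation). Neutrophil markers were higher, 0 over all genes and 13 of 27 adjusted over the list alone (median 1.16, camera adjusted p = 4.5e-08; adjusted p = 0.378 with an estimated correlation). In CPM of library totals, Hbb-bs stood at 4132 ± 1297 in OTUB1_KD and was near 0 in SFD@M replicates 2 and 3 (0.707 and 0.617 CPM) but not in replicate 1 (94.0 CPM).

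Divisions of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real division gave the largest gene count in each comparison (1 of 10), with 9721, 13062, 8977 and 2 genes in OTUB1_KD against NC, SFD@M against Blank, Blank against NC and SFD@M against OTUB1_KD, and 0 at most in the other divisions, which mix groups and so put the differences between groups into the spread. For lists, 3 of 10 divisions called as many as the real 31 in OTUB1_KD against NC (31 at most elsewhere). The real division alone (1 of 10) gave the most in the others, with 33 lists against 32, 22 against 15 and 32 against 26. The correlation between the experiments was taken over 100 pairs, each a division of 1 experiment with a division of the other. It was largest in the real pair (1 of 100, 0.951 against 0.819 at most elsewhere). The other pairs mix groups in at least 1 experiment, which weakens the contrast, so their lower values do not exclude chance division.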
